A study of Mus musculus with 6 samples.

How the data were processed

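Total RNA of decidua from 6 samples was measured, 3 from mice given LPS and 3 from cesarean sections. Per the labels' protocols, RNA was extracted with Trizol and 0.5 μg of it was amplified and labelled with Cy3 by a single-channel kit. Intensity values in the array files, including the background-subtracted and detrended processed signal used here, were made by Agilent Feature Extraction version 12.0.3.1 per the file headers, while the submitters' processing notes give version 9.1. Log2 values in the deposited series matrix have the same minimum and maximum and near-equal medians (4.73 to 4.74) on every array, as quantile normalization gives, and the labels do not state that step. Each column of that matrix correlated best with the array it is named for (lowest r 0.999). Each file held 155279 of 172336 spots of the design, 150305 of them probes other than controls: 47074 for mRNA, 57079 for lncRNA, 37852 for circRNA and 8300 of no stated class.

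Groups were taken from the source names, since the free-text descriptions of the LPS samples name cesarean sections. The labels give all samples as day 17 of pregnancy, although an injection on day 14 and birth about 48 hours later give an earlier day for the LPS samples. The labels do not state that replicates are separate animals, so p-values measure only the spread between samples. The array files place the 3 cesarean arrays and LPS replicate 1 on slide 1, and LPS replicates 2 and 3 on slide 2, with the same split by scan batch.

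The processed signal was put on a log2 scale and the 75th percentile of all probes other than controls was subtracted on each array. Of the 150305 probes, 673 with an outlier flag on any array were dropped, and 95576 that were well above background on all 3 arrays of at least 1 group were kept. Per array, 91470 to 100237 probes were well above background, no spot was saturated, and the slope of the spike-in controls was 0.958 to 0.967. A gene was represented by its brightest kept probe, which gave 18105 genes. Of 7166 genes called, 6776 were well above background on all 6 arrays, 175 have only a bound, and 27 have kept probes called in both directions. Groups were compared with limma 3.58.1 (moderated linear model, Benjamini-Hochberg adjustment, adjusted p under 0.05) in R 4.3.3, and figures were drawn with Matplotlib 3.10.9, NumPy 2.4.6 and pandas 2.3.3 in Python 3.11.15. Where a gene was not well above background on any array of a group, its fold is given as a bound against the array floor.

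The lists, the comparisons, the named genes rule and most alternatives were chosen before the data were examined. Lists were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation. Counts "over the list alone" adjust p within the list only. The 36 lists covered Toll-like receptor and NF-kB signalling, cytokines, chemokines, interferon-stimulated genes, acute phase and complement, antigen presentation, markers of neutrophils, macrophages, dendritic cells, uterine NK cells, T cells, B cells and mast cells, decidual stroma, trophoblast, yolk sac, Y-linked genes, erythroid cells, platelets, myometrium, epithelium and endothelium. They also covered contraction and prostaglandins, steroid hormones, matrix proteases, collagens and matrix, hypoxia, apoptosis and senescence, immediate early genes, heat shock, oxidative stress, the cell cycle, the microRNA machinery, known lncRNAs, the mitochondrial respiratory chain and ribosomal proteins.

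Named genes were the 10 largest rises and 10 largest falls past the threshold whose groups did not overlap, the 2 largest changes per list and direction, and a few genes fixed by name. Ranking was limited to genes well above background on all 6 arrays and left out predicted genes. For lncRNA and circRNA the 5 largest probes per direction were taken, of which the 2 lncRNA IDs per direction are printed. A circRNA was assigned to the gene whose span holds both of its ends. The files do not state a genome build for circRNAs, and 98.2% of their positions lay inside 1 gene span of assembly GRCm38.p6, against 38.5% to 40.8% after shifting them. The circRNA and host changes were correlated with 100000 permutations of the host values.

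The alternatives were other background and scaling methods, other filters on dim probes, slide as a fixed or random block, slide 1 alone, averaging cesarean replicates 2 and 3, leaving out each array, trend and array weights in limma, a 2-fold threshold, the mean of all probes of a gene and an estimated correlation. Chosen after seeing the data were a placental covariate, LPS replicate 3 alone, and limma's fry. Fry tests a list for a shift in a common direction against no change, where camera tests it against other genes. With slide as a fixed block the estimate of a probe compares LPS replicate 1 with the cesarean arrays, as within slide 1, and only the spread differs. Estimates of a gene or list can differ between the 2 where another probe is the brightest within slide 1 (Ly6m, Fasl, Gpx3, Mmp11 and Pcp4 among named genes) or more list members are measured there. In alternatives that take 1 probe per gene the brightest was chosen anew, so a moved value of a gene can come from another probe. The steps were tested on simulated data with known changes. Of simulated 2-fold and 4-fold changes, 14% and 70% were recovered among probes and 42% and 82% among genes, with 4 unchanged probes and 5 unchanged genes called. The simulation changed 50 probes or 50 genes at each fold size, far fewer than the real data called, and gave both groups the same spread. These shares therefore do not give the recovery in the real comparison. A list raised in the simulation was called and no other was, and circRNA and host changes correlated with a rho of 0.0119 when unlinked and 0.965 when linked. Simulated genes varied independently of one another, so the list result does not show how often lists are called where genes correlate. In the real data the estimated correlation reached 0.68 among cell cycle genes.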

Results

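The data were 6 single-channel Agilent arrays of mouse decidua, the maternal tissue of the pregnant uterus, carrying probes for mRNA, long noncoding RNA (lncRNA) and circular RNA (circRNA). Of these, 3 came from mice given lipopolysaccharide (LPS, a bacterial cell wall component) at 100 μg per kg body weight by injection into the abdomen on day 14 of pregnancy. Preterm birth followed after about 48 hours, and decidua was taken once vaginal bleeding was seen. The other 3 came from cesarean sections, and the labels put all 6 samples at day 17 of pregnancy. Each array held 150305 probes other than controls, of which 60.9% (LPS replicate 3) to 66.7% (cesarean replicate 1) were well above background. No probe was saturated. Over the 95576 probes kept, arrays correlated with r from 0.988 to 0.994 within the cesarean group, from 0.972 to 0.982 within the LPS group and from 0.939 to 0.961 between groups. The median SD of a probe was 0.123 on the log2 scale among cesarean arrays and 0.243 among LPS arrays. The number of arrays limits the precision of every value below. The labels name the tissue as decidua, but Y-linked Ddx3y, a gene that maternal tissue lacks, was well above background on all 3 arrays of each group. Yolk sac and visceral endoderm markers had a median normalized log2 signal from 7.74 to 8.51 per array. These signals argue that the samples held fetal tissue as well as decidua, in shares that were not measured. The word decidua below is the labels' name for the samples.

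The comparison asked how RNA levels in decidua after LPS differed from those in decidua of cesarean sections. The LPS samples followed preterm birth and the others surgery, so LPS, birth and the way of collection cannot be told apart. The words "after LPS" name that group and not a cause. After LPS, the lists of interferon-stimulated genes, of Toll-like receptor and NF-kB signalling, of macrophage markers and of immediate early genes shifted higher relative to other genes when genes within a list were taken to correlate at a preset 0.01. These calls were lost with an estimated correlation (adjusted p = 0.321, 0.0764, 0.296 and 0.375 with an estimated correlation). For Toll-like receptor and NF-kB signalling the estimate, -0.017, lay below the preset, so a higher correlation is not what lost that call. Genes that drive cell division were lower, with a median log2 fold change of -2.33 over 38 measured members, as were nuclear genes of the mitochondrial respiratory chain, with a median of -0.58. These list calls were lost as well (adjusted p = 0.436 and 0.510 with an estimated correlation), although 34 of the cell cycle genes and 17 of 25 mitochondrial genes fell when tested singly. Embryonic globins were among the 10 largest falls of genes well above background on all 6 arrays, with Hbb-bh1 40.4-fold lower. The decidual hormone Prl8a2 and the placental hormones differed between arrays of a single group by more than the groups differed, so their values are given array by array below.

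At an adjusted p under 0.05, 2943 of 18105 genes rose and 4223 fell. Among probes, 11093 of 95576 rose and 13501 fell, and 4242 and 6023 of these changed at least 2-fold. By RNA class, 5753 mRNA probes rose and 7712 fell out of 38378, 960 lncRNA probes rose and 2311 fell out of 22198, and 4146 circRNA probes rose and 2944 fell out of 31036. The remaining 3964 probes, whose class the files do not give, held 234 that rose and 534 that fell. The 3 LPS values lay wholly on one side of the 3 cesarean values for 10065 genes, or 55.6%, where chance alone gives 10%. Slide 1 held the 3 cesarean arrays and LPS replicate 1 and slide 2 held LPS replicates 2 and 3, so every value with slide as a block or within slide 1 rests on LPS replicate 1. That sample stood apart, with Xist at 0.06 against 4.10 to 5.50 on the other arrays, and with LPS replicate 2 it was low in Prl8a2, at -3.44. With that block 4143 probes rose, 4632 fell and 3645 genes changed, and within slide 1 alone 7400 probes rose, 9331 fell and 6181 genes changed. Without cesarean replicate 1, 2 or 3, probes that rose numbered 6257, 5075 and 4945, and probes that fell 7322, 5860 and 5668. In the same order mRNA probes changed numbered 8213, 6663 and 6478, and genes 5391, 4489 and 4324. Rises outnumbered falls among probes with quantile normalization (13037 and 12597), with normexp before it (13874 and 13794) and in the series matrix values (12955 and 12704). Averaging cesarean replicates 2 and 3, whose titles share a prefix, left 4547 genes. These 2 arrays correlated with an r of 0.994, against 0.988 and 0.989 with cesarean replicate 1, and may come from 1 animal. If so, cesarean SDs and p-values based on 3 samples count that animal more than once.

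Among genes well above background on all 6 arrays, the largest rise was in Ly6m, a member of the Ly6 family of surface proteins, which was 71.3-fold higher (log2 fold change 6.16, SE 0.83, adjusted p = 0.00248). Among the 10 genes named here Slc10a6 was ahead of it with slide as a fixed or random block, within slide 1, without LPS replicate 2, with array weights and with LPS replicate 3 alone, and Mlph was ahead with normexp. Slc10a6, a transporter of steroid sulfates, rose 61.5-fold, from a normalized log2 signal of -1.84 ± 0.13 (SD, n = 3) in cesarean decidua to 4.10 ± 0.28 (SD, n = 3) after LPS. Serpina3n, an acute phase protease inhibitor, rose 56.4-fold (log2 fold change 5.82, SE 0.65). Mlph, which tethers vesicles to myosin, rose 38.7-fold, and Pglyrp1, which binds bacterial peptidoglycan, rose 38.3-fold. Mal, a membrane protein of epithelia and myelin, rose 34.2-fold and Comp, a matrix glycoprotein of cartilage, rose 31.4-fold. Slc26a3, an anion exchanger of epithelia, Msln, a surface protein of mesothelium, and Igfbp6, which binds insulin-like growth factors, rose 30.0-fold, 29.7-fold and 29.6-fold. Ly6m had a log2 fold change of 3.92 with normexp, 5.16 with slide as a block, 3.26 within slide 1, 5.13 without LPS replicate 2, 7.02 with the placental covariate and 3.20 with LPS replicate 3 alone in place of 6.16. Serpina3n had a log2 fold change of 4.16 with normexp, 4.64 with slide as a block or within slide 1, 6.41 without LPS replicate 1, 5.09 without LPS replicate 2 and 6.56 with the placental covariate in place of 5.82. Slc10a6 had a log2 fold change of 4.90 with normexp in place of 5.94. Pglyrp1 had a log2 fold change of 3.13 with normexp in place of 5.26. Slc26a3 had a log2 fold change of 3.17 with normexp and 4.16 with LPS replicate 3 alone in place of 4.91. Igfbp6 had a log2 fold change of 4.15 with normexp and 4.28 with slide as a block or within slide 1 in place of 4.89. Mal had a log2 fold change of 5.85 with slide as a block or within slide 1 in place of 5.10. With slide as a block, log2 fold changes of the 10 genes ran from 4.28 to 6.19 and all 10 stayed past the threshold. Within slide 1, where another probe of Ly6m was the brightest, they ran from 3.26 to 6.19, also past it.

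Among genes measured in this way the largest fall was in Mbl2, mannose-binding lectin of the complement pathway, which was 62.1-fold lower (log2 fold change -5.96, SE 0.40, adjusted p = 3.36e-04). Among the 10 genes named here Bhmt was lower with slide as a block and within slide 1, and Hsd3b5 was lower without cesarean replicates 1 or 2, without LPS replicates 1 or 2, with array weights and with LPS replicate 3 alone. Hsd3b5 and Hsd3b6, of the hydroxysteroid dehydrogenase family, were 62.0-fold and 28-fold lower. The other kept probe of Hsd3b6 had a log2 fold change of -1.87 against -4.81. Hbb-bh1 and Hba-x, globins of embryonic red cells, fell from 8.58 ± 0.34 to 3.25 ± 0.35 and from 8.74 ± 0.09 to 3.56 ± 0.34 (normalized log2 signal, SD, n = 3 per group). Bhmt, which methylates homocysteine, was 48.8-fold lower, Glyat, which conjugates glycine, was 29.4-fold lower, and Tdh, which breaks down threonine, was 24.6-fold lower. Col9a1, a collagen chain of cartilage, was 34.3-fold lower and Ccdc92b 25.3-fold lower. Mbl2 had a log2 fold change of -5.31 with normexp, -6.67 with slide as a block or within slide 1 and -5.02 with LPS replicate 3 alone in place of -5.96. Bhmt had a log2 fold change of -4.96 with normexp, -6.81 with slide as a block or within slide 1, -5.01 without LPS replicate 1, -6.29 without LPS replicate 3 and -4.25 with LPS replicate 3 alone in place of -5.61. Hsd3b5 had a log2 fold change of -3.52 with normexp in place of -5.95. Ccdc92b had a log2 fold change of -3.38 with normexp in place of -4.66. Col9a1 had a log2 fold change of -4.15 with normexp in place of -5.10. Glyat had a log2 fold change of -4.00 with normexp, -4.25 without LPS replicate 2 and -3.98 with LPS replicate 3 alone in place of -4.88. Hsd3b6 had a log2 fold change of -5.54 with slide as a block or within slide 1 in place of -4.81. Log2 fold changes of these 10 genes ran from -6.81 to -4.31 both with slide as a block and within slide 1, and all 10 stayed past the threshold in both.

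**Figure D1:**
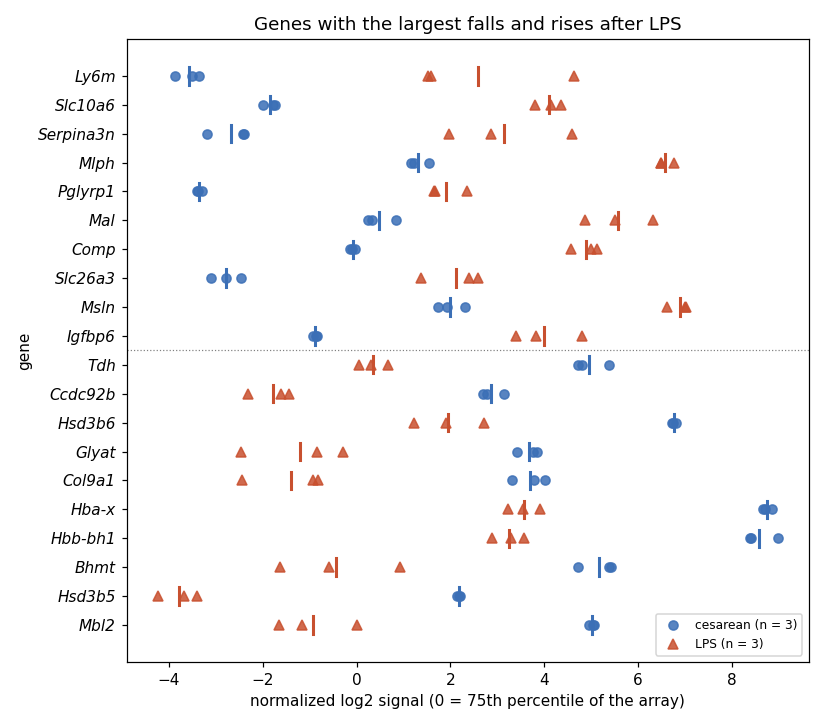
Normalized log2 signal (x axis, 0 = the array's 75th percentile) of the 10 genes with the largest rises and the 10 with the largest falls among genes well above background on all 6 arrays (y axis), with 1 point per array, circles for the 3 cesarean and triangles for the 3 LPS arrays, and bars at the group means. In each gene the LPS points lie wholly to one side of the cesarean points, as for Slc10a6 at 4.35, 4.15 and 3.80 against -1.75, -1.78 and -2.00.

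Among 36 gene lists fixed before the data were examined, 16 moved higher and 3 lower relative to other genes in limma's camera test with a preset correlation of 0.01 between genes. With a correlation estimated for each list none passed, the lowest adjusted p was 0.0764, and 6 lists had an unadjusted p under 0.05. Each list below therefore has its adjusted p with an estimated correlation beside it. For Toll-like receptor and NF-kB signalling, chemokines, matrix proteases and decidual stromal markers the estimate was -0.017, -0.026, -0.004 and 0.003, below the preset. A higher correlation is therefore not what lost those calls. The loss of a call with an estimated correlation does not by itself show that genes of a list correlate. Other splits of the 6 arrays into 3 and 3 called 12 to 19 lists with the preset correlation. The list calls and their adjusted p with the preset therefore do not by themselves show a difference between the LPS and cesarean groups. The median log2 fold change of all genes was -0.10, against which list medians are to be read.

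Interferon-stimulated genes had the highest median of the 36 lists in the main setting. Of 44 measured members, 36 rose, 1 fell and 7 did not pass, with a median log2 fold change of 1.31 (adjusted p = 1.02e-15; adjusted p = 0.321 with an estimated correlation). Adjusted over the list alone, 38 rose and 1 fell. Oasl2, an oligoadenylate synthetase relative, rose 16.0-fold and Ddx60, a helicase of antiviral defence, rose 8.0-fold. The gene that fell, Ifi44l, was well above background on 1 of the 3 LPS arrays and was named after its values were seen. In Toll-like receptor and NF-kB signalling, 20 of 30 rose and none fell, with a median of 0.68 (adjusted p = 1.34e-07; adjusted p = 0.0764 with an estimated correlation), and 21 rose when adjusted over the list alone. Nfkbiz, an inducible regulator of NF-kB, rose 4.11-fold and Clec4e, a receptor of myeloid cells for microbial glycolipids, rose 3.50-fold. Tlr4, the receptor for LPS, rose 2.77-fold (adjusted p = 0.0168). Its call was lost with slide as a block (log2 fold change 1.38 against 1.47), within slide 1, without cesarean replicate 1 or 3 and with LPS replicate 3 alone (adjusted p from 0.00245 to 0.126 over its alternatives). Clec4e had a log2 fold change of 0.67 with normexp in place of 1.81. With slide as a block the interferon and Toll-like receptor medians were 1.21 and 0.61, and within slide 1 1.21 and 0.59.

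Most measured genes of the chemokine and cytokine lists did not pass. Among chemokines and their receptors 8 of 28 rose and 1 fell, with a median of 0.47 (adjusted p = 0.00467; adjusted p = 0.226 with an estimated correlation), and the counts adjusted over the list alone were 8 and 1. Ccl5, which attracts T cells and monocytes, rose 4.68-fold and Cx3cl1, the ligand of a monocyte receptor, rose 3.86-fold. The fall was in Cxcl13, a B cell attractant, well above background on 2 of the LPS arrays and named after its values were seen. Of 23 pro-inflammatory cytokine genes 4 rose and 1 fell, and the list did not pass (median 0.23, adjusted p = 0.0632; adjusted p = 0.375 with an estimated correlation). It did pass with slide as a block, within slide 1, without cesarean replicate 1, without LPS replicate 2 or 3 and in 3 other alternatives (adjusted p from 0.0101 to 0.192 over its alternatives with the preset correlation). Over the list alone 3 rose and 1 fell. The members that rose were Il1rn and Tnfsf9 (log2 fold changes 3.21 and 0.56, named after their values were seen, Il1rn well above background on 2 of the cesarean arrays), Il10 (1.70-fold) and Tgfb1 (1.76-fold), which are known to restrain inflammation, and Il33, an alarm signal of dying cells, fell 1.61-fold. The log2 fold changes of Il1b, Il6 and Tnf, core cytokines of the response to LPS, were 0.86 (SE 0.48), 0.47 (SE 0.42) and 0.02 (SE 0.32), none past the threshold. Il6 passed with slide as a block and within slide 1 (adjusted p from 0.0203 to 0.979 over its alternatives), Il1b with placental markers as a covariate (adjusted p from 0.0345 to 0.726 over its alternatives) and Tnf without LPS replicate 2 and with LPS replicate 3 alone (adjusted p from 0.0331 to 0.996 over its alternatives). Ccl5 had a log2 fold change of 1.24 with normexp, 0.88 with slide as a block or within slide 1 and 2.90 without LPS replicate 1 in place of 2.23. Il6 had a log2 fold change of 1.43 with slide as a block or within slide 1 and -0.01 without LPS replicate 1 in place of 0.47. Tnf had a log2 fold change of 0.00 with normexp, -0.03 without cesarean replicate 1, -0.15 without LPS replicate 1, -0.19 without LPS replicate 3 and -0.24 with the placental covariate in place of 0.02. The chemokine median was 0.27 with normexp or with LPS replicate 3 alone in place of 0.47. Ccl5 lost its call without cesarean replicate 1, 2 or 3, without LPS replicate 3 and with cesarean replicates 2 and 3 averaged (adjusted p from 8.97e-04 to 0.0687 over its alternatives), Il10 without cesarean replicate 1, 2 or 3, with cesarean replicates 2 and 3 averaged, with LPS replicate 3 alone, with placental markers as a covariate and in 1 other alternative (adjusted p from 0.0165 to 0.127 over its alternatives), Tgfb1 with slide as a block (log2 fold change 0.70 against 0.81) and within slide 1 (adjusted p from 0.00188 to 0.0620 over its alternatives) and Il33 with slide as a block (log2 fold change -0.63 against -0.69), without cesarean replicate 2 or 3, with cesarean replicates 2 and 3 averaged and with LPS replicate 3 alone (adjusted p from 0.00925 to 0.136 over its alternatives).

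Acute phase and complement genes moved in both directions. Of 29 acute phase and complement genes 13 rose and 5 fell, with a median of 0.57 (adjusted p = 0.00225; adjusted p = 0.296 with an estimated correlation), or 16 and 5 over the list alone. Saa3, a serum amyloid made by macrophages and stroma, rose 15.1-fold beside Serpina3n, while Hp and Serpina1a, both typical liver products, fell 3.14-fold and 3.15-fold. The other falls, named after their values were seen, were in C1s1 (2.15-fold), Crp (1.80-fold) and Ptx3, which was well above background on 2 of the LPS arrays. Serpina1a had a log2 fold change of -1.03 with LPS replicate 3 alone in place of -1.66. Serpina1a lost its call with slide as a block (log2 fold change -1.70 against -1.66, adjusted p from 0.00252 to 0.0559 over its alternatives). Slide-block medians were 0.26 for cytokines, 0.51 for chemokines and 0.47 for acute phase genes, and within slide 1 0.26, 0.55 and 0.47.

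Among markers of myeloid cells and genes of antigen presentation, rises outnumbered falls. Of 28 monocyte and macrophage markers 17 rose and 1 fell, with a median of 0.91 (adjusted p = 1.34e-07; adjusted p = 0.296 with an estimated correlation), and 19 and 1 over the list alone. Cd163, the hemoglobin scavenger receptor, rose 5.17-fold and Arg1, arginase, rose 4.62-fold, while Mrc1, the mannose receptor, fell 1.56-fold. Of 20 antigen presentation genes 11 rose and none fell (median 1.03, adjusted p = 2.32e-05; adjusted p = 0.194 with an estimated correlation), 12 of them over the list alone, led by the nonclassical histocompatibility genes H2-T23 (3.98-fold) and H2-Q7 (3.43-fold). The other kept probe of H2-Q7 had a log2 fold change of 0.23 against 1.78. Of 31 neutrophil markers 8 rose and 3 fell (median 0.79, adjusted p = 0.00287; adjusted p = 0.375 with an estimated correlation), with the same counts over the list alone. Stfa2l1, a stefin, rose 5.66-fold and Il1r2, a decoy receptor for interleukins, rose 4.35-fold, whereas Chil3 fell 2.39-fold, Cxcr1 1.66-fold and Padi4, named after its values were seen, 1.48-fold. Stfa2l1 had a log2 fold change of 1.02 with normexp, 1.70 without LPS replicate 2, 3.20 with the placental covariate and 1.42 with LPS replicate 3 alone in place of 2.50. Il1r2 had a log2 fold change of 1.5 with normexp and 2.93 with slide as a block or within slide 1 in place of 2.12. The neutrophil median was 0.46 with normexp, 0.49 with slide as a block and 0.47 within slide 1 in place of 0.79. Mrc1 lost its call with slide as a block (log2 fold change -0.37 against -0.65), within slide 1, without cesarean replicate 1, 2 or 3 and with cesarean replicates 2 and 3 averaged (adjusted p from 0.00824 to 0.162 over its alternatives), Stfa2l1 with slide as a block (log2 fold change 1.99 against 2.50), without cesarean replicate 1, 2 or 3, with cesarean replicates 2 and 3 averaged, with LPS replicate 3 alone and in 1 other alternative (adjusted p from 0.00522 to 0.223 over its alternatives) and Il1r2 with LPS replicate 3 alone (adjusted p from 0.00937 to 0.0843 over its alternatives). Chil3 lost its call with slide as a block (log2 fold change -0.88 against -1.26), within slide 1, without cesarean replicate 2 or 3, without LPS replicate 2 or 3, with cesarean replicates 2 and 3 averaged, with LPS replicate 3 alone, with placental markers as a covariate and in 2 other alternatives (adjusted p from 0.0242 to 0.308 over its alternatives) and Cxcr1 with slide as a block (log2 fold change -0.36 against -0.73), within slide 1, without cesarean replicate 1, 2 or 3, without LPS replicate 2 and with cesarean replicates 2 and 3 averaged (adjusted p from 0.00953 to 0.271 over its alternatives). Slide-block medians were 0.77, 0.71 and 0.49 for the macrophage, antigen presentation and neutrophil lists, and 0.77, 0.71 and 0.47 within slide 1.

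Lists of lymphoid, dendritic and mast cells did not pass. Of 20 uterine NK cell markers none rose and 4 fell (median -0.54, adjusted p = 0.333; adjusted p = 0.742 with an estimated correlation), 3 of them over the list alone. Klra4, Klra15 and Klra1, Ly49 receptors of NK cells that were not among these markers, were higher after LPS and were named after their values were seen. Gzma, a granzyme, fell 1.53-fold and Fasl 1.40-fold. Gzma lost its call with slide as a block (log2 fold change -0.47 against -0.61) and without cesarean replicate 3 (adjusted p from 0.00867 to 0.113 over its alternatives) and Fasl with slide as a block (log2 fold change -0.35 against -0.49), without cesarean replicate 1, 2 or 3, without LPS replicate 2 or 3, with cesarean replicates 2 and 3 averaged and in 8 other alternatives (adjusted p from 0.00686 to 0.820 over its alternatives). Eomes, a transcription factor of NK cells and trophoblast that was not well above background on any LPS array and was named after its values were seen, was at least 1.96-fold lower, and Prf1, perforin, also named after its values were seen, fell and was well above background on 2 of the LPS arrays. Of 16 T cell markers 1 rose, Cd28 (named after its values were seen, well above background on 2 of the cesarean arrays), and 2 fell, Lck and Lat, both of T cell receptor signalling (median -0.23, adjusted p = 0.847; adjusted p = 0.886 with an estimated correlation). Of 9 B and plasma cell markers Mzb1 fell 1.65-fold and none rose (median -0.14, adjusted p = 0.847; adjusted p = 0.886 with an estimated correlation). Of 11 dendritic cell markers 2 rose, Bst2 and Itgax, and 1 fell, Fscn1, with a median of -0.06 and a mean of -0.17 although the test pointed upward (adjusted p = 0.847; adjusted p = 0.886 with an estimated correlation). Of 13 mast cell and eosinophil markers 1 rose, Ccr3, and 2 fell, the mast cell protease Mcpt4 (4.21-fold) and Mcpt8, named after its values were seen and well above background on 2 of the LPS arrays, again with a median (-0.04) and mean (-0.03) below 0 and a test that pointed upward (adjusted p = 0.870; adjusted p = 0.941 with an estimated correlation). Mcpt4 had a log2 fold change of -0.30 with normexp, -0.87 with cesarean replicates 2 and 3 averaged and -1.46 without cesarean replicate 2 in place of -2.07. Fasl had a log2 fold change of -2.02 within slide 1 and -2.80 with LPS replicate 3 alone in place of -0.49, both from another probe. The 3 kept probes of Fasl had log2 fold changes from -2.88 to -0.49. The other kept probe of Ccr3 had 0.47 against 1.52. Itgax lost its call with slide as a block (log2 fold change 0.78 against 0.73) and without cesarean replicate 1 or 2 (adjusted p from 0.00869 to 0.0849 over its alternatives) and Mcpt4 without cesarean replicate 2, with cesarean replicates 2 and 3 averaged and in 1 other alternative (adjusted p from 6.13e-04 to 0.554 over its alternatives). Counts over the list alone were 1 and 2 for T cells, 0 and 1 for B cells, 2 and 1 for dendritic cells and 1 and 2 for mast cells. Over all alternatives the medians ran from -0.94 to -0.07 for NK cells (-0.14 without LPS replicate 3 and -0.33 without cesarean replicate 1), and they turned sign for T cells (-0.26 to 0.01), B cells (-0.26 to 0.05), dendritic cells (-0.28 to 0.10) and mast cells (-0.82 to 0.08). Slide-block medians of the NK, T, B, dendritic and mast cell lists were -0.36, 0.01, 0.02, -0.14 and 0.08, and those within slide 1 were -0.42, 0.01, 0.05, -0.14 and 0.05.

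Cell division genes fell almost throughout. Of 38 cell cycle genes 34 fell and none rose (adjusted p = 1.48e-10; adjusted p = 0.436 with an estimated correlation), with 1 up and 35 down over the list alone. Ccnb1, the mitotic cyclin, was 12.9-fold lower and Kif11, the spindle motor, 10.7-fold lower. Ccnb1 had a log2 fold change of -3.04 with slide as a block or within slide 1 and -3.09 without LPS replicate 2 in place of -3.69. Kif11 had a log2 fold change of -2.49 with slide as a block or within slide 1 and -2.81 without LPS replicate 2 in place of -3.42. Of 33 genes of apoptosis, p53 and senescence 9 rose and 5 fell (median 0.15, adjusted p = 0.0443; adjusted p = 0.436 with an estimated correlation), or 10 and 6 over the list alone, and the list lost its call without cesarean replicate 1, without LPS replicate 1, with LPS replicate 3 alone and in 3 other alternatives (adjusted p from 0.0138 to 0.0990 over its alternatives with the preset correlation). Its median was 0.09 with normexp, 0.29 with slide as a block or within slide 1, 0.24 without LPS replicate 2, 0.10 without LPS replicate 3 and 0.06 with array weights in place of 0.15. Cdkn1a, which stops the cell cycle, rose 3.67-fold and Igfbp7, a secreted senescence factor, 3.98-fold, while Lmnb1, a nuclear lamina protein lost in senescence, fell 3.33-fold and Cdkn2c 2.58-fold. The other falls, named after their values were seen, were in Bcl2l11, Casp3 and Gdf15 (log2 fold changes -0.69, -0.75 and -0.83). Cdkn2c lost its call with slide as a block (log2 fold change -1.20 against -1.37, adjusted p from 0.00175 to 0.0539 over its alternatives). Of 25 nuclear genes of the mitochondrial respiratory chain 17 fell and none rose (adjusted p = 3.84e-05; adjusted p = 0.510 with an estimated correlation), 19 over the list alone, including Cycs, cytochrome c (2.11-fold), and Ppargc1a, a regulator of mitochondrial number (3.44-fold). Ppargc1a had a log2 fold change of -1.18 with normexp and -1.15 with LPS replicate 3 alone in place of -1.78, and the mitochondrial median was -0.36 with LPS replicate 3 alone in place of -0.58. Of 35 ribosomal protein genes only Rpl30 fell (1.44-fold, and not over the list alone), none rose, and the list did not pass (median -0.08, adjusted p = 0.498; adjusted p = 0.886 with an estimated correlation). Rpl30 lost its call with slide as a block (log2 fold change -0.40 against -0.53), within slide 1, without cesarean replicate 2 or 3, with cesarean replicates 2 and 3 averaged and with LPS replicate 3 alone (adjusted p from 0.00677 to 0.161 over its alternatives), and the ribosomal list passed, downward, in 3 other alternatives (adjusted p from 0.00566 to 0.874 over its alternatives with the preset correlation). Slide-block medians were -1.89, 0.29, -0.57 and -0.12 for the cell cycle, apoptosis, mitochondrial and ribosomal lists, and the same within slide 1.

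Immediate early genes, which cells switch on within minutes of a stimulus, rose in 22 of 28 members with none lower (median 1.12, adjusted p = 1.78e-10; adjusted p = 0.375 with an estimated correlation), 23 over the list alone. Fos rose 8.81-fold and Egr1 6.25-fold. Of 25 genes of the heat shock and unfolded protein responses 10 rose and 8 fell, with the same counts over the list alone, and the list did not pass (median 0.30, adjusted p = 0.131; adjusted p = 0.540 with an estimated correlation). Hspa1a, the inducible chaperone of the cytosol, rose 4.90-fold and Chac1 2.98-fold, while the mitochondrial chaperones Hspe1 and Hspd1 fell 2.34-fold and 2.18-fold. Of 24 genes of oxidative stress and metal response 2 rose and 6 fell, also over the list alone (median -0.21, adjusted p = 0.245; adjusted p = 0.751 with an estimated correlation). Gsta3, a glutathione transferase, was 11.3-fold lower and Nqo1 2.91-fold lower, and the extracellular peroxidase Gpx3 rose 1.89-fold and its cytosolic relative Gpx1 1.37-fold. Of 32 hypoxia and glycolysis genes 8 rose and 6 fell, 9 and 6 over the list alone (median 0.08, adjusted p = 0.167; adjusted p = 0.510 with an estimated correlation), with Pfkfb3, an activator of glycolysis, 4.25-fold and Egln3, an oxygen sensor, 4.02-fold higher, and Car12 2.71-fold and Pfkl 1.68-fold lower. Gsta3 had a log2 fold change of -2.75 with LPS replicate 3 alone in place of -3.50. Car12 had a log2 fold change of -0.78 with normexp in place of -1.44, and its other kept probe had -3.45. Chac1 lost its call with slide as a block (log2 fold change 1.10 against 1.57, adjusted p from 0.00177 to 0.0602 over its alternatives), Hspe1 with slide as a block (log2 fold change -1.08 against -1.23, adjusted p from 0.00102 to 0.0505 over its alternatives) and Gpx1 with slide as a block (log2 fold change 0.29 against 0.45), within slide 1, without cesarean replicate 1, 2 or 3, without LPS replicate 2 or 3, with cesarean replicates 2 and 3 averaged, with LPS replicate 3 alone, with placental markers as a covariate and in 2 other alternatives (adjusted p from 0.0144 to 0.237 over its alternatives). The heat shock list passed without LPS replicate 1 (adjusted p from 0.0455 to 0.523 over its alternatives with the preset correlation) and the oxidative stress list with the series matrix values (adjusted p from 0.0458 to 0.683 over its alternatives with the preset correlation). Slide-block medians were 1.04, 0.12, -0.17 and 0.10, and 1.07, 0.12, -0.17 and 0.10 within slide 1. Without LPS replicate 2 the heat shock median was 0.14 in place of 0.30. The hypoxia median was 0.13 without LPS replicate 2 and 0.04 without LPS replicate 3 in place of 0.08.

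**Figure D2:**
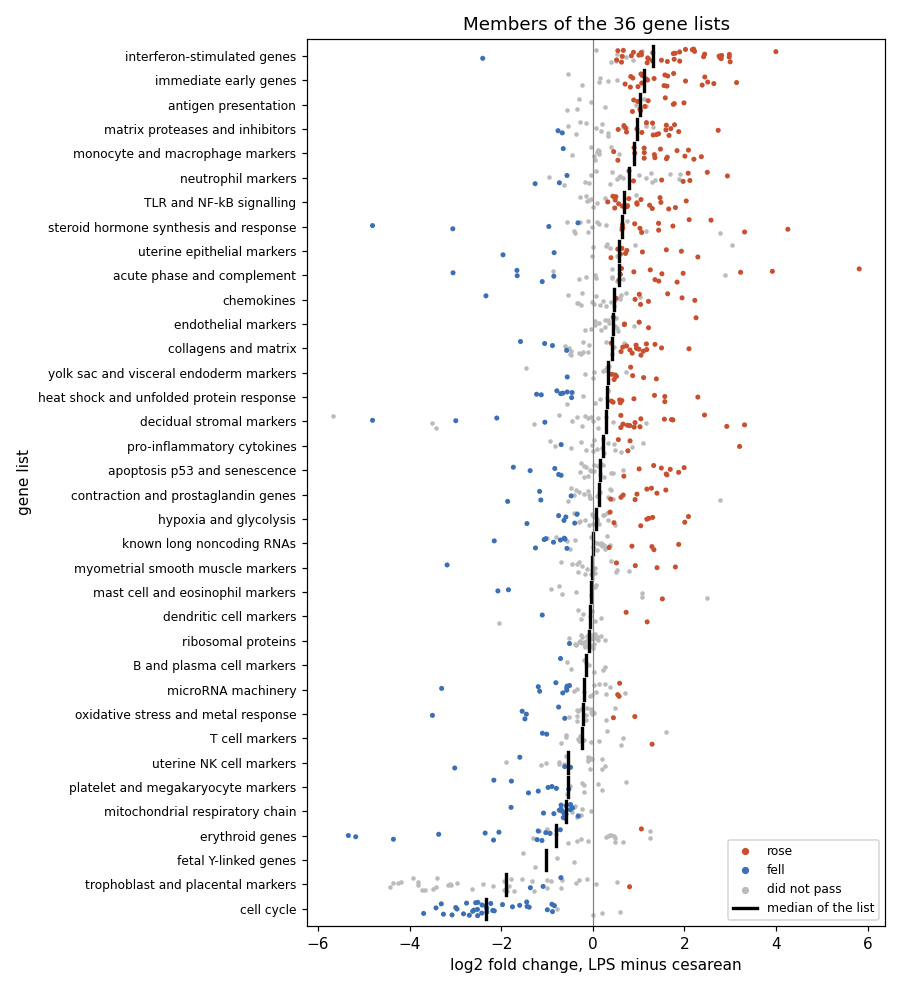
Log2 fold change (x axis, LPS minus cesarean) of each measured member of the 36 gene lists (y axis, ordered by median), with members that rose in red, members that fell in blue, members that did not pass in grey and a black bar at each list's median. Medians run from -2.33 for cell cycle genes to 1.31 for interferon-stimulated genes.

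Steroid metabolism changed in both directions. Of 31 genes of steroid hormone synthesis and response 14 rose and 4 fell, also over the list alone (median 0.64, adjusted p = 0.00287; adjusted p = 0.375 with an estimated correlation). The list lost its call within slide 1 (adjusted p from 0.00121 to 0.129 over its alternatives with the preset correlation). Its median was 0.31 with normexp, 0.20 with slide as a block, 0.17 within slide 1 and 0.34 without LPS replicate 2 in place of 0.64. Hsd11b1, which regenerates active glucocorticoid, rose 19.1-fold (log2 fold change 4.26, SE 0.42, adjusted p = 9.39e-04) and Hsd11b2, which inactivates it, fell 8.32-fold (log2 fold change -3.06, SE 0.34, adjusted p = 0.00130). Cyp11a1, which makes pregnenolone from cholesterol, rose 9.95-fold, while Hsd3b6 fell, as did Hsd17b7 and Pgrmc1 (1.95-fold and 1.25-fold, named after their values were seen). Pgr, the progesterone receptor, was well above background on 1 of the 6 arrays, an LPS array, and could not be compared. Hsd11b1 had a log2 fold change of 3.67 with LPS replicate 3 alone in place of 4.26. Hsd11b2 had a log2 fold change of -2.36 with LPS replicate 3 alone in place of -3.06.

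Decidual genes did not move as a block. Of 37 decidual stromal markers 15 rose and 4 fell, 16 and 6 over the list alone, and the median (0.30) and the test pointed upward while the mean was -0.08 (adjusted p = 0.0253; adjusted p = 0.296 with an estimated correlation). The list lost its call with slide as a block, within slide 1, without LPS replicate 3 and in 1 other alternative (adjusted p from 0.0135 to 0.25 over its alternatives with the preset correlation), with a median of 0.17 with slide as a block, 0.22 within slide 1, and 0.18, 0.17 and 0.46 without LPS replicates 1, 2 and 3 in turn. Cyp11a1 and Bmp8a, a bone morphogenetic protein, rose, the latter 7.59-fold, and Hsd3b6 and Hoxa11, a homeobox gene of the uterus, fell, the latter 7.95-fold. The other falls, named after their values were seen, were in Igfbp5 (4.28-fold) and Fst (2.06-fold). Hoxa11 lost its call without cesarean replicate 1, 2 or 3, without LPS replicate 3 and with cesarean replicates 2 and 3 averaged (adjusted p from 0.00150 to 0.0561 over its alternatives). Hoxa11 had a log2 fold change of -1.39 with normexp, -4.41 with slide as a block or within slide 1, -2.28 without LPS replicate 1, -3.78 without LPS replicate 2 and -2.34 with the placental covariate in place of -2.99. Bmp8a had a log2 fold change of 2.11 with normexp in place of 2.93. Prl8a2, the decidual prolactin relative, had a normalized log2 signal of 5.52, 5.58 and 5.44 on the cesarean arrays and 5.76 in LPS replicate 3, but -3.44 and -2.78 in LPS replicates 1 and 2 (log2 fold change -5.66, SE 2.35, adjusted p = 0.102). Prl8a2 passed within slide 1 and without LPS replicate 3 (adjusted p from 5.47e-04 to 0.242 over its alternatives), and its log2 fold change was -8.95 with slide as a block but 0.25 with LPS replicate 3 alone. Every decidual, immune and stromal value here was measured in samples that differed in this way.

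Rises outnumbered falls among epithelial, endothelial and matrix genes, although many members did not pass. Of 20 epithelial markers 10 rose and 2 fell, also over the list alone (median 0.57, adjusted p = 2.71e-04; adjusted p = 0.375 with an estimated correlation). Cldn3, a tight junction protein, rose 4.90-fold and the transcription factor Klf5 3.82-fold, and the epithelial regulators Ehf and Esrp1 fell 3.89-fold and 1.79-fold. Of 23 endothelial markers 6 rose and none fell, also over the list alone (median 0.45, adjusted p = 2.71e-04; adjusted p = 0.439 with an estimated correlation), with Vcam1, an adhesion molecule for leukocytes, 4.77-fold and Eng 2.33-fold higher. The endothelial median was 0.21 with slide as a block or within slide 1 and 0.28 without LPS replicate 2 in place of 0.45. Of 33 matrix proteases and inhibitors 18 rose and 2 fell, 21 and 2 over the list alone (median 0.96, adjusted p = 2.09e-06; adjusted p = 0.0764 with an estimated correlation). Ctss, a cathepsin of antigen-presenting cells, rose 3.67-fold and the metalloprotease Mmp19 3.26-fold, while Mmp11 and Adamts9 fell 1.69-fold and 1.59-fold. Of 35 collagens and other matrix genes 16 rose and 4 fell, 18 and 4 over the list alone (median 0.43, adjusted p = 0.00631; adjusted p = 0.439 with an estimated correlation). Col8a1 rose 4.29-fold and Eln, elastin, 2.83-fold, while Vcan, versican, and Postn, periostin, fell 2.99-fold and 2.07-fold, as did Col5a2 and Lamb1 (1.49-fold and 1.84-fold, named after their values were seen). Col8a1 had a log2 fold change of 1.38 with slide as a block or within slide 1 in place of 2.10, and the median of matrix proteases was 0.51 with normexp in place of 0.96. Ehf lost its call with slide as a block (log2 fold change -1.5 against -1.96), within slide 1, without LPS replicate 3, with LPS replicate 3 alone and in 1 other alternative (adjusted p from 0.00646 to 0.196 over its alternatives), Mmp11 with slide as a block (log2 fold change -0.74 against -0.76) and without cesarean replicate 3 (adjusted p from 0.00666 to 0.0895 over its alternatives), Adamts9 with slide as a block (log2 fold change -0.53 against -0.67), within slide 1, without cesarean replicate 1, 2 or 3, without LPS replicate 3, with cesarean replicates 2 and 3 averaged and in 5 other alternatives (adjusted p from 0.0216 to 0.228 over its alternatives) and Postn with slide as a block (log2 fold change -0.61 against -1.05), within slide 1 and without cesarean replicate 1 (adjusted p from 0.00352 to 0.122 over its alternatives). Slide-block medians were 0.42, 0.21, 0.66 and 0.30 for these lists in turn, and the same within slide 1.

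Genes of uterine contraction gave no uniform picture. Of 31 contraction and prostaglandin genes 9 rose and 4 fell, 9 and 5 over the list alone, and the list did not pass (median 0.14, adjusted p = 0.131; adjusted p = 0.375 with an estimated correlation). Ptgs1, the constitutive prostaglandin synthase, rose 3.02-fold and the prostaglandin receptor Ptger4 2.64-fold, while Abcc4, an exporter of prostaglandins, and Cacna1c, a calcium channel, fell 3.63-fold and 2.19-fold, as did the prostaglandin receptor Ptgfr (2.24-fold, named after its values were seen). Oxtr, the oxytocin receptor, fell 1.39-fold (adjusted p = 0.0397), and lost its call with slide as a block (log2 fold change -0.29 against -0.47), within slide 1, without cesarean replicate 1, 2 or 3, without LPS replicate 2 or 3, with cesarean replicates 2 and 3 averaged, with LPS replicate 3 alone and in 4 other alternatives (adjusted p from 0.0290 to 0.296 over its alternatives). The log2 fold changes of Ptgs2, the inducible prostaglandin synthase, and Gja1, the gap junction protein of labor, were -0.36 (SE 0.23, adjusted p = 0.265) and 0.44 (SE 0.23, adjusted p = 0.180). Gja1 passed with slide as a block and within slide 1 (adjusted p from 0.0180 to 0.419 over its alternatives). Of 21 myometrial smooth muscle markers 4 rose, with Myh11, smooth muscle myosin, 3.49-fold and Lmod1 2.65-fold higher, beside Mylk and Sorbs1 (1.90-fold and 1.43-fold, named after their values were seen), and Pcp4 fell 9.07-fold, with the same counts over the list alone. The median of that list was -0.02 and its mean 0.05, with a test that pointed upward (adjusted p = 0.364; adjusted p = 0.510 with an estimated correlation), and the median ran from -0.05 to 0.09 over all alternatives. Slide-block medians were 0.12 and 0.08, and the same within slide 1. The contraction median was 0.07 without LPS replicate 3, 0.01 with LPS replicate 3 alone and 0.06 with normexp in place of 0.14.

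Placental and fetal genes differed between arrays within both groups. The median normalized log2 signal of 43 trophoblast and placental markers was 3.98, 4.20 and 3.49 in cesarean replicates 2 and 3 and LPS replicate 2, against -1.38, -2.63 and -1.76 in cesarean replicate 1 and LPS replicates 1 and 3. In that list 1 rose, Peg10 (1.75-fold), and 3 fell, with Hand1 2.57-fold and Phlda2 2.12-fold lower and Xlr3b, named after its values were seen, 1.62-fold lower, and the list did not pass (median -1.89, adjusted p = 0.0975; adjusted p = 0.840 with an estimated correlation). It did pass, downward, with slide as a block, within slide 1, without cesarean replicate 1, without LPS replicate 2, with LPS replicate 3 alone and in 1 other alternative (adjusted p from 2.74e-04 to 0.623 over its alternatives with the preset correlation), with a median of -3.06 with slide as a block and -3.02 within slide 1. Leaving out an array gave medians from -4.08 (cesarean replicate 1) to -0.96 (LPS replicate 1). With the placental covariate, which is built from these markers, the median was 0.21. Adjusted over the list alone, 1 rose and 3 fell. None of the 4 Y-linked genes passed (median -1.02, adjusted p = 0.610; adjusted p = 0.886 with an estimated correlation; slide-block and slide 1 median 0.48), and the log2 fold changes of Uty and Ddx3y were -1.53 (SE 0.93) and -1.25 (SE 0.92). Ddx3y stood at -1.21 in LPS replicate 2 and between 1.56 and 2.66 on the other 5 arrays. It passed with LPS replicate 3 alone (adjusted p from 0.0173 to 0.804 over its alternatives). With slide as a block the log2 fold changes of Uty and Ddx3y turned to 0.06 and 0.40. The median of the Y-linked list was -0.05 without LPS replicate 2 and -1.76 without LPS replicate 1. Of 22 yolk sac and visceral endoderm markers 8 rose and 1 fell, 9 and 2 over the list alone (median 0.34, adjusted p = 0.00159; adjusted p = 0.439 with an estimated correlation; slide-block and slide 1 median 0.29). Their median signal was high on every array, from 7.74 to 8.51, and Alb, albumin, and Apoa1 rose 2.62-fold and 2.16-fold while Apoa2 fell 1.47-fold. Apoa2 lost its call with slide as a block (log2 fold change -0.76 against -0.56), without cesarean replicate 1, 2 or 3, without LPS replicate 1 or 2, with cesarean replicates 2 and 3 averaged and with LPS replicate 3 alone (adjusted p from 0.00450 to 0.123 over its alternatives).

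Of 34 erythroid genes 13 fell and 1 rose, Tspo2 (2.09-fold), with 2 up and 13 down over the list alone. The list did not pass (median -0.81, adjusted p = 0.0632; adjusted p = 0.631 with an estimated correlation). It did pass, downward, with slide as a block, within slide 1, without LPS replicate 2 and in 7 other alternatives (adjusted p from 0.00188 to 0.343 over its alternatives with the preset correlation), with a median of -1.16 with slide as a block and within slide 1. Hbb-bh1 and Hba-x led the falls. Of 16 platelet and megakaryocyte markers 8 fell and none rose, 9 over the list alone (median -0.54, adjusted p = 0.0426; adjusted p = 0.510 with an estimated correlation; slide-block and slide 1 median -0.70). Tubb1, the tubulin of platelets, fell 4.47-fold and Treml1 3.43-fold. The platelet list lost its call without cesarean replicate 1, 2 or 3, without LPS replicate 1 or 3, with cesarean replicates 2 and 3 averaged, with placental markers as a covariate and in 4 other alternatives (adjusted p from 0.00469 to 0.150 over its alternatives with the preset correlation). Its median was -0.31 with normexp and -0.83 without LPS replicate 2 in place of -0.54. Tubb1 had a log2 fold change of -0.91 with normexp and -2.91 with slide as a block or within slide 1 in place of -2.16. Treml1 had a log2 fold change of -2.44 with slide as a block or within slide 1 in place of -1.78.

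**Figure D3:**
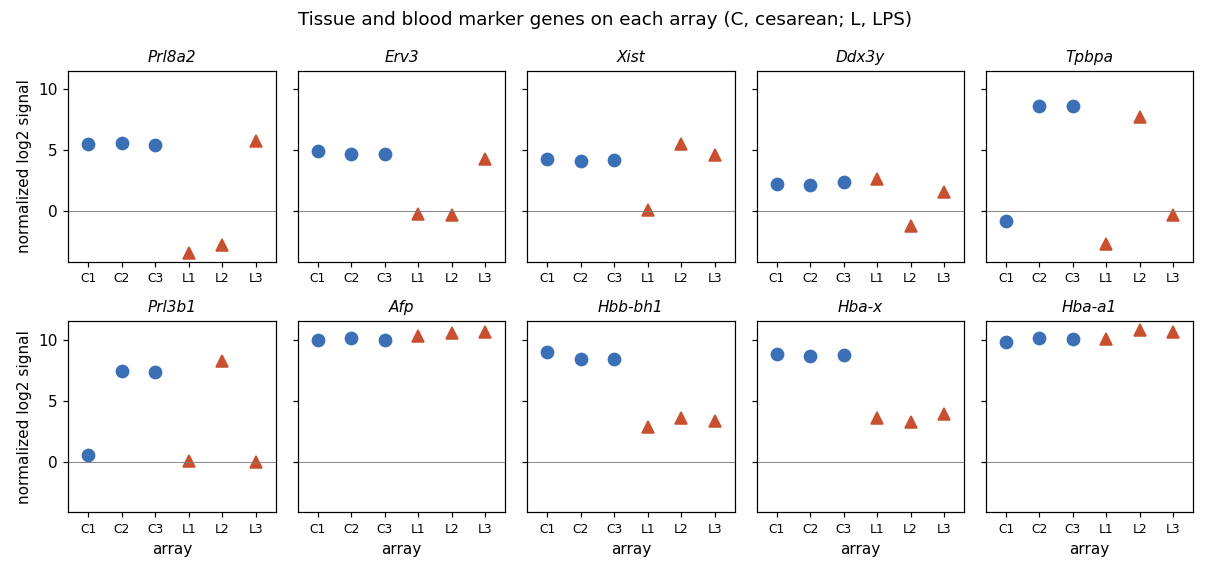
Normalized log2 signal (y axis) of marker genes on each array (x axis; C, cesarean; L, LPS; 1 point per array). Prl8a2 and Erv3 are low in LPS replicates 1 and 2 (Prl8a2 at -3.44 and -2.78), Xist is low in LPS replicate 1, the placental genes Tpbpa and Prl3b1 are high in cesarean replicates 2 and 3 and LPS replicate 2, and the embryonic globins Hbb-bh1 and Hba-x separate the groups while Hba-a1 does not.

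Long noncoding RNAs fell more often than they rose. Of 22198 lncRNA probes tested, 29.3% of the calls were rises, against 42.7% for mRNA probes and 58.5% for circRNA probes, and the differences between classes were not tested. With other scalings the share was 31.5% to 42.2% for lncRNA, 43.9% to 45.3% for mRNA and 60.6% to 66.7% for circRNA probes. Most lncRNA probes carry transcript IDs that the files do not pair with gene names. Among those well above background on all 6 arrays, NONMMUT117756 and NONMMUT082709 had the largest rises (14.3-fold and 13.2-fold), and NONMMUT134026 and NONMMUT019392 the largest falls (54.0-fold and 31.8-fold). Among 32 known long noncoding RNAs that carry symbols 5 rose and 9 fell, 5 and 10 over the list alone. Neat1, the scaffold of nuclear paraspeckles, rose 3.67-fold and Dleu2 2.52-fold, with Lncpint, Malat1 and H19 (2.45-fold, 1.81-fold and 1.28-fold, named after their values were seen) also higher, while Gas5 and Snhg14, both hosts of small nucleolar RNAs, fell 2.38-fold and 4.44-fold. The list did not pass, and its median was 0.01, its mean -0.13 and its test upward (adjusted p = 0.870; adjusted p = 0.886 with an estimated correlation; slide-block median -0.08, slide 1 median -0.04, and -0.08 to 0.09 over all alternatives). Snhg14 had a log2 fold change of -1.18 with normexp and -2.94 with LPS replicate 3 alone in place of -2.15. By log2 fold change, NONMMUT117756 had 3.19 with LPS replicate 3 alone in place of 3.84, NONMMUT082709 had 1.72 with normexp and 2.69 with slide as a block or within slide 1 in place of 3.72 and NONMMUT134026 had -3.66 with normexp and -5.16 with slide as a block or within slide 1 in place of -5.76. Snhg14 lost its call with slide as a block (log2 fold change -2.08 against -2.15, adjusted p from 0.00130 to 0.0602 over its alternatives). The count of lncRNA probes changed, 3271, was 5675 without LPS replicate 1, 1632, 1358 and 1313 without cesarean replicates 1, 2 and 3 in turn, and 1160 with slide as a block.

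The series set out to profile RNAs that could compete for microRNAs. Of 25 genes of the microRNA machinery 3 rose and 9 fell, 3 and 10 over the list alone, and the list did not pass (median -0.19, adjusted p = 0.544; adjusted p = 0.682 with an estimated correlation; slide-block and slide 1 median -0.36). The median was -0.09 without cesarean replicate 3, -0.11 without LPS replicate 1 and -0.29 without LPS replicate 3. Ran, the nuclear transport GTPase, and Dgcr8, a subunit of the microprocessor, fell 2.28-fold and 2.23-fold, while Tut7, a uridylyltransferase, and Adar, an RNA editing enzyme, rose 1.5-fold and 1.49-fold, as did Ago2 (1.46-fold, named after its values were seen). Dgcr8 lost its call with slide as a block (log2 fold change -0.82 against -1.16, adjusted p from 0.00271 to 0.0712 over its alternatives) and Adar with slide as a block (log2 fold change 0.50 against 0.57), without cesarean replicate 1, 2 or 3 and with cesarean replicates 2 and 3 averaged (adjusted p from 0.0104 to 0.131 over its alternatives).

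Among circRNA probes, 13.4% of those tested rose and 9.49% fell. Among those well above background on all 6 arrays, the largest rise lay within Itgb6, an epithelial integrin, on chromosome 2 from 60600338 to 60620433 (19.1-fold, SE 0.13 on the log2 scale), and another Itgb6 circRNA, from 60605140 to 60620433, rose 16.1-fold. The circRNAs within Msln on chromosome 17 rose 16.3-fold and 12-fold, and a circRNA within the amino acid transporter gene Slc3a1 rose 10.1-fold. In the same set the 5 largest falls lay within Top2a (8.85-fold), Spag5 (8.76-fold), Cenpf (8.58-fold), Spc25 (8.46-fold) and Bub1b (8.42-fold). The circRNA within Spc25 lost its call with slide as a block (adjusted p from 8.48e-04 to 0.0791 over its alternatives). The log2 fold change of that circRNA was -2.46 without LPS replicate 2 in place of -3.08. With normexp the log2 fold changes of the 5 circRNAs that rose ran from 2.27 to 3.61, and those of the 5 that fell from -2.31 to -1.61. Those within Spc25, Top2a and Spag5 had, with slide as a block, -2.36, -2.52 and -2.52. The count of circRNA probes changed, 7090, was 1915 with slide as a block and 4045 within slide 1. Without cesarean replicate 1, 2 or 3 it was 3258, 2541 and 2453.

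The circRNA probes moved with the mRNA of the gene they lie in. Across 29369 circRNA probes in 6192 host genes the log2 fold changes of circRNA and host mRNA correlated with a Spearman rho of 0.653 and a Pearson r of 0.642 (two-sided permutation p = 1e-05 for each, the smallest that 100000 resamples can give). The correlation is across probes and genes, which are not independent replicates. Both the circRNA probe and the host mRNA passed in 5007 cases, and in 4926 of these, or 98.4%, they moved in the same direction. The slope of the circRNA on the host change was 0.58. The host mRNAs of the 5 falls named above had log2 fold changes from -3.26 (Bub1b) to -2.76 (Top2a), and Itgb6 and Msln had 4.30 and 4.89.

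**Figure D4:**
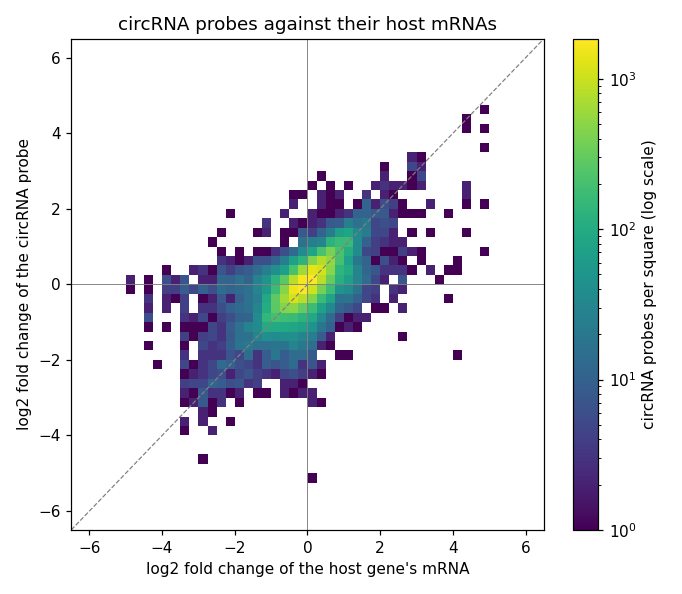
Log2 fold change (LPS minus cesarean) of each circRNA probe (y axis) against that of its host gene's mRNA (x axis), as counts of probes per square of 0.25 by 0.25 on a log colour scale, with a dashed line where both changes are equal. The 29369 probes spread along a rising band with a slope of 0.58.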

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

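The placental covariate, LPS replicate 3 alone and limma's fry were chosen after seeing the data. No paired analysis was possible because the labels give the groups no shared replicate numbers. Within slide 1 and with LPS replicate 3 alone, the lone LPS sample is assumed to vary like the cesarean group. Of probes on an array 60.9% to 66.7% were well above background, which limits what was measured. Of 119 named genes past the threshold, 89 passed in every alternative run on them and 30 lost the call in at least 1. No call of a named gene, named probe or list reversed, but among the 7166 genes called, 3 were called in the opposite direction within slide 1, 3 with LPS replicate 3 alone, 1 without LPS replicate 2 and 4 with the mean of all probes of a gene. Of 19 lists called, 15 were called in every alternative but the estimated correlation, and 11 of the 17 not called were called in none with camera.

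With slide as a fixed block, 4143 probes rose and 4632 fell, with 5364 mRNA, 1160 lncRNA and 1915 circRNA probes and 3645 genes changed, and 3407 of the 7166 genes kept their call and direction. That estimate, like those within slide 1, rests on LPS replicate 1, the sample with low Xist and Prl8a2. With cesarean replicates 2 and 3 averaged, which leaves 1 sample fewer, the counts were 5412 and 6097, then 6995, 1393 and 2735, and 4547 genes. Within slide 1, with fewer samples, 4045 circRNA probes changed. Without a filter on dim probes, which tests more probes, 4555 circRNA probes changed, and the lowest correlation within a group exceeded the highest between groups by 0.00129 (0.0104 in the main setting). A 2-fold threshold added to the adjusted p left 4242 and 6023 probes by its construction. With LPS replicate 3 alone 6373 lncRNA probes changed, and the cause was not tested. With an estimated correlation 0 lists passed in limma's camera, and 6 had an unadjusted p under 0.05. Fry asks another question, whether a list shifted in a common direction against no change rather than against other genes. It called 25: the 19 and the cytokine, erythroid, heat shock, hypoxia, microRNA machinery and oxidative stress lists.

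Leaving out each array in turn gave 4945 to 13218 probes that rose and 5668 to 18678 that fell, 6478 to 15027 mRNA, 1313 to 5675 lncRNA and 2453 to 10082 circRNA probes changed, and 4324 to 7582 genes changed. The lowest of each came without cesarean replicate 3 and the highest without LPS replicate 1, and the cause was not tested.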

Other observations

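The tests on Xist and Prl8a2, the placental covariate and the genes named in this paragraph were chosen after the values were seen. Among genes well above background in a single group were Klra4, Klra15 and Klra1, NK cell receptors of the Ly49 family. They were at least 40.1-fold, 22.7-fold and 14.3-fold higher after LPS, and Klra20, Klra8 and Klra9 at least 10.9-fold, 7.59-fold and 5.57-fold. Near-identical members of that family can share probe signal, and none of these genes was a measured member of the uterine NK cell list. Krt78, a keratin, was at least 20.9-fold higher, and Lilr4b at least 11.2-fold. Lrrc19 was at least 30.5-fold lower, Cpn2 at least 18.7-fold and Pah, which hydroxylates phenylalanine, at least 15.3-fold.

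Of 43 placental markers 37, or 86.0%, were highest in LPS replicate 2 among the LPS arrays, and a different share of placental tissue per sample may account for this. Xist was lower in LPS replicate 1 than on any other array by at least 4.03 on the log2 scale over its 4 probes. Little female tissue in that sample may be the reason, and decidua itself is female tissue. Little decidua in LPS replicates 1 and 2 cannot be told apart from a change in Prl8a2 itself, since 6 of 36 other decidual markers, or 16.7%, were lower in both than on the other 4 arrays (exact 95% interval 6.37% to 32.8%) and 8 were higher in both. With the placental markers as a covariate 6356 of 7166 genes kept their call and direction.

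Embryonic globins fell while no adult globin passed (median log2 fold change 0.39), so less blood of any kind in the LPS samples is argued against: the median log2 fold change of adult globins exceeded that of embryonic globins by 5.56, and the lowest adult value exceeded the highest embryonic value by 3.64. Younger fetal tissue in the cesarean samples cannot be told apart from other causes. Genes known to fall as fetal tissue ages had a median of -0.50, but of 8 genes 4 fell and 2 rose. Hmga2, Trim71, Igf2bp1 and Hmga1 fell (log2 fold changes -3.31, -1.43, -1.38 and -0.77), and Igf2bp2 and Mycn rose (0.80 and 0.61). The stage label gives both groups the same day. Injection on day 14 and birth about 48 hours later would instead make the LPS samples the younger ones. These labels conflict, so they do not decide the question.

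The circRNA changes may be carried by signal of the linear host mRNA or by shared transcription, since they correlated with those of the host with a rho of 0.653. Shared transcription predicts the same value, and the labels name no step that removes linear RNA. Of the circRNA probes called, 1784 lay in a host whose mRNA did not pass.

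The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split and the highest other gave 24594 and 39 probes changed, 13465 and 36 mRNA, 3271 and 1 lncRNA and 7090 and 0 circRNA probes, and 7166 and 41 genes, so 1 split gave as many calls in each. For gene lists the values were 19 and 19, so 2 splits gave as many, and the other splits called 12 to 19 lists. The other split with 19 lists set cesarean replicate 1 with LPS replicates 2 and 3 against the rest, and slide 2 holds those LPS arrays. A split with those LPS arrays on opposite sides, cesarean replicates 1 and 2 with LPS replicate 3, called 18. About as many list calls thus arose without a split by slide or by group. With slide as a block 21 lists were called.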
